A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

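The deposited data were 1 table with a value for each of 10928 probe sets in 2 samples, 1 mock and 1 alpha factor. Per the labels' protocols, total RNA was extracted with hot acidic phenol, treated with DNase, checked for integrity, labelled with biotin and hybridised to Affymetrix Yeast 2.0 arrays. Groups were taken from the sample titles and source names. The free-text description of the mock sample repeats that of the treated sample, and was not used. The deposited values were taken as log2 expression values, since they ran from 3.32 to 15.19 and the sorted columns differed by at most 0.092. The authors used the affy package of Bioconductor, per the labels and the submitters' processing notes; its version, the background correction, the normalization and the summary of probes into probe sets are not given in the sources used here. No source used here records a scaling between the arrays. A scaling that makes 2 columns this alike would remove any change in total mRNA, so ratios are relative to the average gene. Levels near the top of the scale leave little room for an increase, so ratios of genes that are bright in both arrays can be compressed. Exactly equal values in both arrays were found for 287 probe sets.

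Genes were named through the platform annotation given for the probe sets, matched by gene ID to the RefSeq table of assembly R64. Of all probe sets, 7244 had 1 gene, 1 had several and 3683 were unnamed here, of which 213 are array controls. A named probe set whose gene ID was in the S. cerevisiae table was taken as S. cerevisiae (5498), and any other as S. pombe (1747). The symbols of 12 probe sets were updated. No genome build is named for the array values, so no coordinates are given and the table was used for names and for which genes neighbour each other. The probe sets of 1 gene were averaged on the log2 scale, which concerned 47 of 5449 genes. For 125 genes at least 1 probe set carries a name ending that marks a match to several transcripts, and their values are uncertain.

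The background level of each array was the 95th percentile of its S. pombe probe sets, 5.50 in both. The arrays come without detection calls, so this level stands in their place. A gene was called higher or lower when its log2 ratio was at least 1 in size and its level was above background in at least 1 array. A gene below background in the dimmer array has only a bound, which was computed against the background level. No pseudocount was added. With 1 array per group there is no replicate check, no p-value and no standard error. As the only repeat measure within the arrays, the log2 ratios of 45 pairs of probe sets naming 1 gene differed with an SD, divided by the square root of 2, of 0.404. Many of these pairs read near-identical families, and the value is not a replicate error.

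Before the data were examined, 30 gene lists, the rule for named genes and most alternatives were fixed. Named were the deleted genes, the 15 genes with the largest and the 15 with the lowest log2 ratio above background, up to 5 members of each list with the largest ratios, members that go against their list, and the alpha-specific and reference genes in full. Any other gene is named as chosen after its value was seen. For each list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 20 bins. This percentile describes these 2 arrays and is not a test between conditions. Genes of 1 list can vary together, which the random lists leave out, so an extreme percentile can go with a small median. List members for which no probe set is named here were not analysed. The calling and the percentile were tested on simulated data for the count of genes 2-fold or more higher or lower: of 5449 genes, 200 were changed by a log2 ratio of 2 or 3 in either direction with noise of SD 0.186 taken from the S. pombe probe sets. These sizes lie far from the 2-fold rule relative to that noise, so that all 200 were called and none of 5249 unchanged genes was, which says nothing about calls near 2-fold. In a second simulation, of 50 genes each, 43 changed by a log2 ratio of 1.2 in size and 50 changed by 1.5 were called, as were 6 changed by 0.8 and 0 changed by 0.5. Genes near the rule can therefore be missed or called by noise. This noise is that of background signal and leaves out differences between cultures.

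Alternatives were other centrings (S. cerevisiae or S. pombe median at 0), quantile normalization, removal of a loess curve, the brightest probe set per gene, other background levels, a pseudocount of 32, fold rules of 1.5 and 4, and other random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.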

Results

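Transcript levels were measured in Saccharomyces cerevisiae, budding yeast, of the a mating type, in 1 mock-treated culture and in 1 culture that had been given the mating pheromone alpha factor. Alpha factor is the peptide that cells of the alpha mating type secrete, and cells of the a type answer it by stopping the cell cycle before S phase and growing a mating projection. The treated culture received 50 ng/ml of the peptide for 3 hours. How the mock culture was grown is not given in the sources used here. Both cultures were of 1 S288c-derived strain that lacks BAR1, the secreted protease that degrades alpha factor, and carries deletions in URA3, LEU2, HIS3 and MET15. Total RNA from each culture was hybridised to 1 Affymetrix Yeast 2.0 array, a single-colour oligonucleotide array that carries probe sets for S. cerevisiae and for the fission yeast S. pombe. With 1 array per condition there was no replicate error for any value and no test between the conditions, and the number of arrays limits the precision of every ratio. Ratios are alpha factor over mock, and a gene is called higher or lower only by a rule of size, a ratio of 2-fold or more in a gene whose level was above the background level in at least 1 array.

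The 5498 S. cerevisiae probe sets named here had a median expression value of 10.68 (log2) in the mock array and 10.65 in the alpha-factor array. The 1747 S. pombe probe sets were assumed to match no transcript in these cultures and had medians of 4.48 in both arrays. Their 95th percentiles of 5.50 in each array were taken as the background level. Of 5449 S. cerevisiae genes, 5337 were above that level in at least 1 array. None of the S. pombe probe sets differed by 2-fold between the arrays, and 95% of their log2 ratios lay between -0.38 and 0.35. This range describes signal near background and does not stand for the spread between cultures. Across S. cerevisiae probe sets, which are not independent replicates, the arrays correlated with a Pearson r of 0.941 and a Spearman rho of 0.926. Control probe sets gave measures of RNA quality. The 3' minus 5' difference of 7 control transcripts changed by a median of 0.03 between the arrays, while 2 probe sets of 25S ribosomal RNA, of which 1 is named for the 3' end, were at a median of 14.73 in the mock array and 9.70 in the alpha-factor array. These 2 were chosen after their values were seen. The log2 ratios of all 8 probe sets of 25S ribosomal RNA ran from -5.20 to 0.01, with a median of -0.85.

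The genes deleted in the strain were examined first. BAR1 was at 3.83 in the mock array and 3.63 in the alpha-factor array, below the background level in both. URA3, which encodes the last enzyme of uridine monophosphate synthesis, was at 4.47 and 4.41, and LEU2, a leucine biosynthesis gene, was at 5.01 in the mock array with a log2 ratio of -0.01. MET17, the current name of MET15, was at 5.48 and 5.46, just under the background level. HIS3 was at 11.81 in the mock array and 12.21 in the alpha-factor array. The his3Δ1 allele removes only part of the gene, so a probe set outside the deleted part checks nothing. Where the HIS3 probe set lies was not examined, so the arrays leave the state of HIS3 open. Both cultures are of the same strain, so these 5 genes do not tell the conditions apart. The median log2 ratio of the 5 was -0.02, at percentile 62.20 of the random lists described with the mating genes.

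The comparison of the treated with the mock culture asked which transcripts change when a cells respond to pheromone. With alpha factor, 294 genes (5.51% of those above background) were higher by 2-fold or more and 202 (3.78%) were lower. Of the 15 genes with the largest ratios, 9 were on the list of mating and cell fusion genes. Of the 15 with the lowest ratios, 5 were on the list of G1/S genes, 3 were on the list of G2/M genes, and 7 were on none of the lists. A ratio of 8-fold or more was reached by 25 higher and 18 lower genes.

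**Figure D1:**
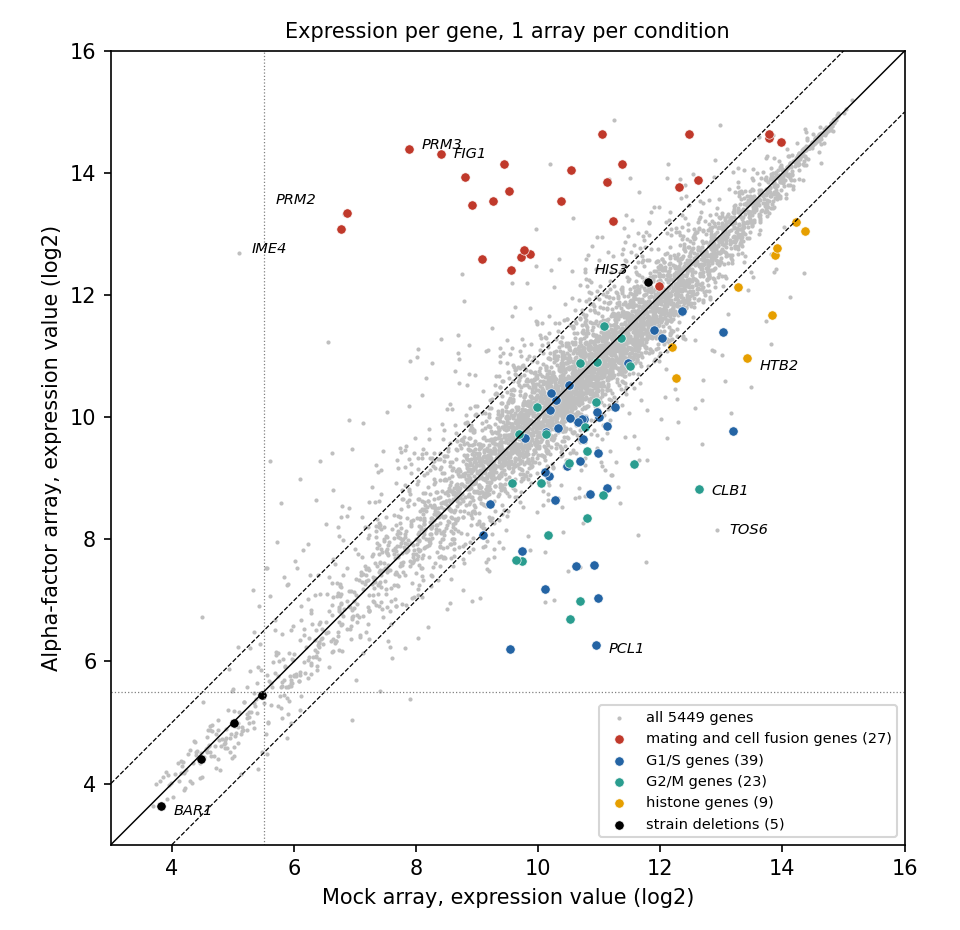
Expression value of each of 5449 genes in the mock array (x axis, log2) against the alpha-factor array (y axis, log2), 1 array per condition. The solid line marks equality, the dashed lines a 2-fold ratio and the dotted lines the background level of 5.50; 23 of 27 mating genes lie above the dashed lines, histone and many G1/S and G2/M genes lie below them, and BAR1 lies below background in both arrays.

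Genes of mating and cell fusion were higher as a group. Of 27 listed genes, 23 were higher by 2-fold or more and none was lower, and the other 4 also had ratios above 1. The median log2 ratio of the list was 2.97, at percentile 100 of 10000 random gene lists of the same size and expression level, whose medians lay between -0.21 and 0.09 in 95% of draws. PRM3, a nuclear envelope protein needed for karyogamy, was 91.3-fold higher, from 7.89 to 14.40. PRM2 was 89.8-fold higher, PRM6 was 79.5-fold higher, and FIG1, a membrane protein of the calcium influx that accompanies mating, was 59.9-fold higher. PRM1, which acts in plasma membrane fusion, was 34.9-fold higher, ASG7 was 26.1-fold higher, and FUS2, a cell fusion protein, was 23.7-fold higher. AFR1, which shapes the mating projection, was 19.6-fold higher and PRM8 was 18.4-fold higher. Among members named after their values were seen, FUS1 was 6.64-fold higher, the karyogamy kinesin KAR3 was 6.98-fold higher, and its partner CIK1 was 11.5-fold higher. The members below 2-fold were the a-factor genes MFA1 and MFA2, the a-factor exporter STE6 and the cell wall protein SCW10. Their mock levels were 13.77, 13.97, 11.98 and 13.77, and their log2 ratios were 0.87, 0.54, 0.18 and 0.79.

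Other genes among the 15 with the largest ratios fell outside the mating list. IME4, an mRNA methyltransferase gene known from meiosis, had the largest ratio of all genes. It was below background in the mock array at 5.09 and at 12.68 in the alpha-factor array, so it was at least 145-fold higher when set against the mock background level. Its log2 ratio of 7.59 became 6.64 with a pseudocount of 32, which lowers the ratios of dim genes. The annotation lists an antisense RNA, RME2, across the whole of IME4, and the strand that the IME4 probe set reads was not examined. Open reading frames of the retrotransposon Ty3 were also among them, YGR109W-A at 91.3-fold, YGR109W-B at 15.6-fold and YIL082W-A at 12.4-fold. The probe sets of YGR109W-A and YIL082W-A match more than 1 transcript, so the share of each Ty3 copy is uncertain. BAG7, a GTPase-activating protein for Rho1, was 25.8-fold higher, and the uncharacterised reading frame YNL042W-B was 12.8-fold higher from a mock level of 5.60, close to background. That log2 ratio of 3.68 became 3.02 with the pseudocount.

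Of 18 components of the pheromone signalling pathway, 3 were higher by 2-fold or more, none was lower, and the median log2 ratio was 0.28, at percentile 99.65. The higher genes were DIG2, an inhibitor of the transcription factor Ste12, at 4.56-fold, FUS3, the MAP kinase of the pathway, at 3.67-fold, and FAR1, the cyclin-dependent kinase inhibitor and polarity adaptor, at 2.38-fold. GPA1 and STE18, the alpha and gamma subunits of the receptor's G protein, had ratios of 1.93-fold and 1.92-fold. Of 8 negative regulators, 3 were higher by 2-fold or more and none was lower. These were the MAP kinase phosphatase MSG5 at 3.77-fold, the regulator of G protein signalling SST2 at 3.25-fold, and the tyrosine phosphatase PTP2 at 3.06-fold. PTP3 had a log2 ratio of -0.58 and YCK2 one of -0.32, and the list's median was 0.00, at percentile 66.25.

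Genes that mark mating types were listed to describe which cells the cultures held. Of 7 a-specific genes, ASG7 and the agglutinin subunit gene AGA2 (2.42-fold) were higher by 2-fold or more. STE2, the alpha-factor receptor, had a log2 ratio of 0.52 from a mock level of 13.72. The list, which also holds the deleted BAR1, had a median of 0.54, at percentile 99.97. Of 4 alpha-specific genes, MF(ALPHA)2, a minor alpha-factor gene, was 4.84-fold higher, from 6.37 to 8.64, and STE3, the a-factor receptor of alpha cells, was 3.38-fold higher, from 7.74 to 9.49. SAG1, the alpha-agglutinin gene, was at 9.53 and 9.91. MF(ALPHA)1, the major alpha-factor gene of alpha cells, was at 5.85 and 5.93. This list's median was 1.07, at percentile 99.62. Of 32 meiosis and sporulation genes, 7 were not above background in either array, 3 were higher by 2-fold or more and 2 were lower, with a median log2 ratio of 0.07 at percentile 85.22. SPO11, the nuclease that starts meiotic recombination, was 7.26-fold higher, CDA1 was 3.69-fold higher and SPO22 was 2.22-fold higher. SPO16 was 3.75-fold lower and was at 5.51 with alpha factor, close to background. Its log2 ratio became -1.39 with a pseudocount of 32. SPS4, below background with alpha factor, was at least 2.73-fold lower, with a log2 ratio of -1.90 that became -1.26 with that pseudocount.

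Genes of the G1/S transition and of DNA replication were lower as a group. Of 39 measured genes, 21 were lower by 2-fold or more and none was higher, and the median log2 ratio was -1.03, at percentile 0.0 of the random lists. The G1 cyclin PCL1 was 25.5-fold lower, from 10.94 to 6.27. YOX1, a homeodomain repressor, was 15.3-fold lower. RNR1, the large subunit of ribonucleotide reductase, was 10.7-fold lower, the cohesin subunit gene MCD1 was 10.1-fold lower, and the S-phase cyclin CLB6 was 9.98-fold lower. CLN1 and CLN2, G1 cyclins named after their values were seen, were 8.33-fold and 2.96-fold lower. The lowest ratio of all genes was that of TOS6, which encodes a cell wall protein and was 27.3-fold lower. NRM1, a repressor of G1/S genes, was 8.83-fold lower. All 9 measured histone genes were lower by 2-fold or more, with a median log2 ratio of -1.22, at percentile 0.0. HTB2 was 5.47-fold lower, the linker histone gene HHO1 was 3.09-fold lower, and HTB1 was 2.48-fold lower. HTA2 was 4.42-fold lower as the mean of 2 probe sets, which differed. The brighter, shared one alone gave a log2 ratio of -1.08. HHF1 was 2.33-fold lower and was read by a probe set that can also match its near-identical copy.

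Genes transcribed in G2 and mitosis were lower in 12 of 23 cases and higher in none. Their median log2 ratio was -1.12, at percentile 0.0. HOF1, a cytokinesis protein, was 14.2-fold lower, the mitotic cyclin CLB1 was 13.9-fold lower, and the transcription factor SWI5 was 13.0-fold lower. BUD4 was 5.48-fold lower and the septum chitin synthase CHS2 was 5.07-fold lower. Of 18 genes of the M/G1 interval and of daughter cells, 8 were lower by 2-fold or more and 1 was higher, with a median of -0.53 at percentile 0.0. The lower genes included EGT2, which acts in cell separation, at 8.49-fold, the cell wall protein PIR1 at 6.14-fold, and the cyclin PCL9, with a log2 ratio of -2.32. The higher gene was TEC1, a transcription factor of filamentous growth, at 2.16-fold. Of 9 genes of the MCM cluster, the replication licensing factor CDC6 was 4.85-fold lower, and the others stayed within 2-fold. CLN3, a G1 cyclin, had a log2 ratio of 0.51. The list's median was -0.40, at percentile 1.8. MCM6 was just short of the 2-fold rule and passed it after quantile normalization, which made 2 lower members.

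Genes of cell wall integrity were higher in 10 of 23 cases and lower in none, with a median log2 ratio of 0.89 at percentile 100. GSC2, which encodes a glucan synthase and is also called FKS2, was 6.75-fold higher. SLT2, the MAP kinase of the cell wall integrity pathway, was 5.38-fold higher, and its pseudokinase paralogue KDX1 was 3.21-fold higher. CRG1 was 7.83-fold higher and the surface protease YPS3 was 3.59-fold higher. Genes of polarity and the mating projection did not share a direction. Of 20, RVS161, an amphiphysin-like protein needed for fusion, was 3.01-fold higher, and GIC1, an effector of Cdc42, was 8.07-fold lower. The polarisome scaffold SPA2 had a log2 ratio of -0.91 and AXL1, a protease that matures a-factor, one of 0.99. The median was -0.15, at percentile 20.45. After centring on either median or removal of a loess curve, AXL1 passed the 2-fold rule and the list had 2 higher members. Of 12 filamentous growth genes, 3 were higher by 2-fold or more and none lower, namely the protease YPS1 at 3.54-fold, TEC1, and the pectinase PGU1 at 2.03-fold. FLO11, the flocculin of filamentous growth, had a log2 ratio of -0.80, and the list's median was -0.03, at percentile 49.67.

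General stress genes were higher in 9 of 29 cases and lower in 1, and 27 had a ratio above 1. Their median log2 ratio was 0.71, at percentile 100. The glycogen phosphorylase GPH1 was 2.91-fold higher, the glycogen branching enzyme GLC3 was 2.85-fold higher and the trehalase NTH1 was 2.67-fold higher. The hexokinase HXK1 was 2.80-fold higher and the nicotinamidase PNC1 was 2.82-fold higher. YGP1, a secreted glycoprotein, was the lower member, with a log2 ratio of -1.12. Genes of ribosome biogenesis had small ratios in a shared direction. None of 38 reached 2-fold, but all 38 had a ratio below 1, with a median log2 ratio of -0.45 at percentile 0.0. The largest was that of NOP7, at -0.83. The 128 genes taken by name as ribosomal protein genes had a median log2 ratio of 0.00 and lay between -0.60 and 0.25, at percentile 75.06, or 98.94 when matched on the mock level. The lowest of them, RPP1, is a subunit of ribonuclease P that the name rule also took. The median level of this list was 14.41 in both arrays, near the top of the scale. Ratios can be compressed there, so a change of these genes is not excluded.

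Of 14 phosphate genes, 4 were lower by 2-fold or more, none was higher and 10 were neither, with a median of -0.49 at percentile 0.01. These were the acid phosphatase genes PHO5 at 5.33-fold and PHO11 at 4.25-fold, the transport regulator SPL2 at 3.35-fold, and the polyphosphate synthesis gene VTC3 at 2.32-fold. The probe set of PHO11 also matches a near-identical copy, and PHM8 had a log2 ratio of 0.74. Of 18 iron regulon genes, 4 were lower by 2-fold or more, none was higher and 14 were neither, with a median of -0.42 at percentile 0.13. These were the high-affinity iron permease FTR1 at 5.34-fold, its oxidase FET3 at 3.95-fold, the siderophore transporter SIT1 at 3.80-fold and the low-affinity transporter FET4 at 3.33-fold. The heme oxygenase HMX1 had a log2 ratio of 0.87. Of 8 listed hexose transporter genes, whose median was -0.06 at percentile 47.44, HXT1, a low-affinity transporter, was 4.46-fold lower and HXT5 was 3.25-fold higher. The list does not hold every HXT gene. HXT11, outside it and named after its value was seen, had a log2 ratio of 2.81. Glycolysis genes were within 2-fold except TDH1, a glyceraldehyde-3-phosphate dehydrogenase, at 4.11-fold higher. The median of 16 glycolysis genes was 0.04, at percentile 99.01, or 77.37 against lists not matched on level. Their median levels were 14.77 in the mock array and 14.80 in the alpha-factor array, where ratios can be compressed.

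Other metabolic lists held few genes past 2-fold. Of 37 respiration genes, the citrate synthase CIT1 was 2.27-fold higher, LSC2 was 2.01-fold higher and the cytochrome c gene CYC1 was 2.60-fold lower. Their median was 0.21, at percentile 99.93. Of 15 gluconeogenesis and glyoxylate genes, POT1 had a log2 ratio of 1.14 from a mock level below background, which bounds its change at 1.98-fold or more. That list's median was 0.35, at percentile 99.24, or 96.61 when matched on the mock level, and the list had 0 higher members with a pseudocount of 32 or with levels below background raised to it. With that pseudocount the respiration list had 1 higher member. Of 37 amino acid genes controlled by Gcn4, 5 were higher and LYS20 was 2.46-fold lower, with a median of -0.04 at percentile 54.82. The higher ones included SNO1 at 3.94-fold and SNZ1 at 3.05-fold, neighbouring genes of vitamin B6 synthesis, and the ornithine transporter ORT1 at 3.10-fold. SNO1 started from 5.55, close to background, and its log2 ratio of 1.98 became 1.46 with a pseudocount of 32. Of 25 methionine and sulfur genes, the sulfate permease SUL1 was 2.75-fold higher and MET28 was 2.61-fold higher, with a median of 0.17 at percentile 98.12, or 96.95 when matched on the mock level. SUL1 started from 5.61, close to background, and its log2 ratio of 1.46 became 1.04 with that pseudocount. None of 15 listed unfolded protein response genes and none of 23 listed ergosterol genes reached 2-fold. Their medians were 0.25 at percentile 99.62 and 0.02 at percentile 85.28. The ergosterol list leaves out ERG24, an ergosterol gene that was listed with the mating genes. Named after its value was seen, ERG24 was higher, with a log2 ratio of 1.47. Of 23 genes taken by their COS, PAU or SEO names, COS111 was 2.37-fold and COS7 2.17-fold higher. COS111 was taken by its name only and is not a member of the COS family. COS7 was read by a shared probe set, and near-identical members of the families make single values uncertain. The median of the 23 genes was 0.28, at percentile 99.45.

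Genes used as references were all within 2-fold. ACT1, the actin gene, had a log2 ratio of 0.15, PDA1 one of 0.04, SPT15 one of -0.05, ALG9 one of -0.08 and UBC6 one of -0.09. FAA1, TAF10, TUB2, TUB1 and TAF8 had log2 ratios of -0.17, -0.19, -0.22, -0.39 and -0.45. The widest were TFC1 at -0.76 and TRS65, listed as KRE11, at 0.78. The list's median was -0.13, at percentile 19.99.

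**Figure D2:**
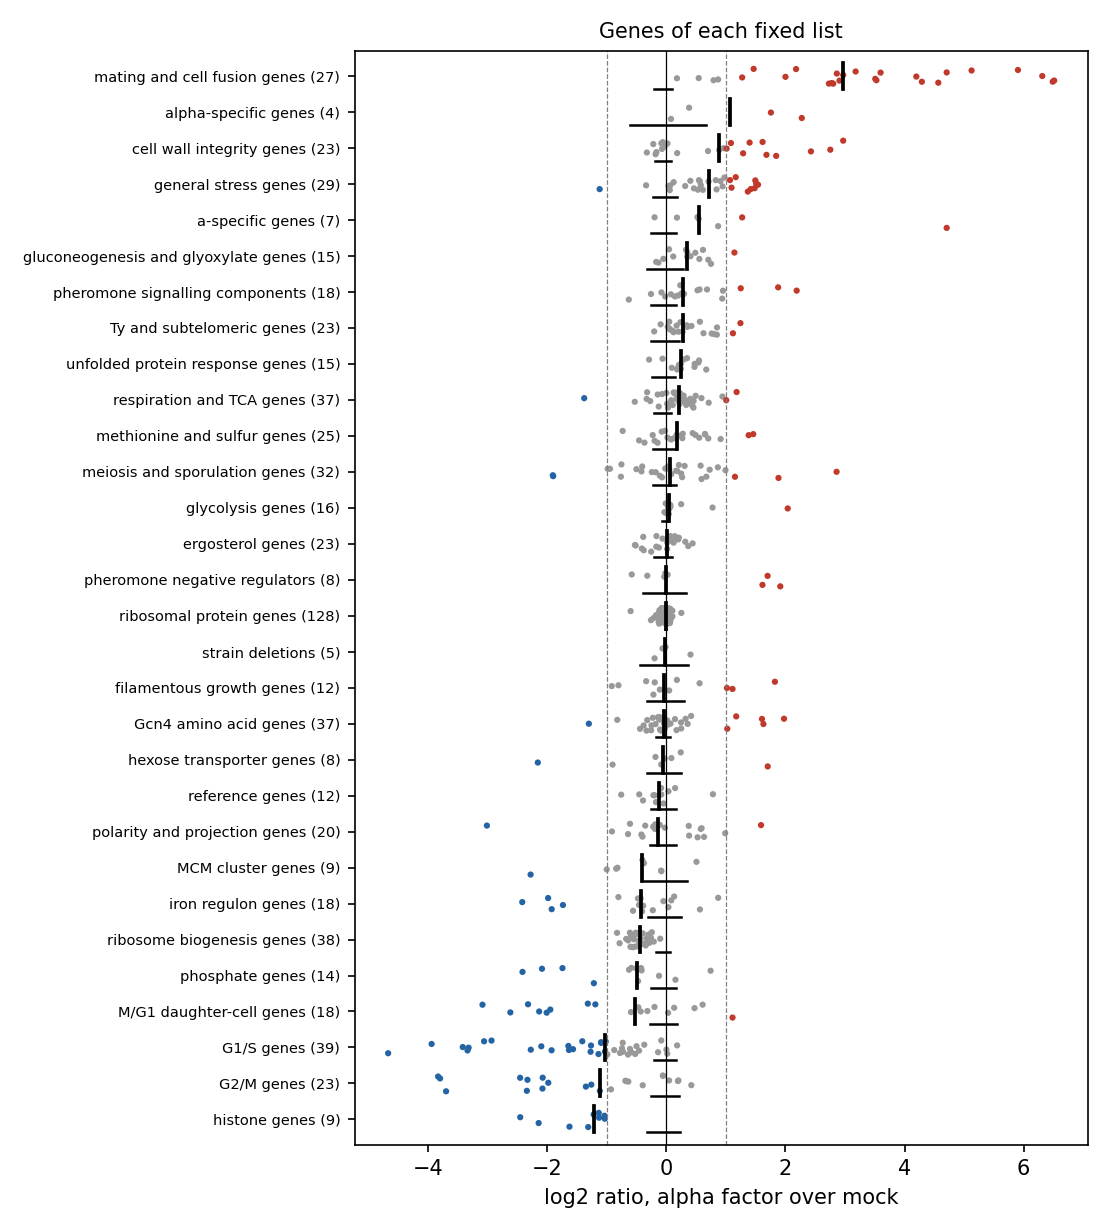
log2 ratio of alpha factor over mock (x axis) for the genes of 30 lists fixed beforehand (y axis, measured genes in parentheses). Points are genes, red where higher and blue where lower by 2-fold or more, the thick tick is the list's median, and the thin bar holds 95% of the medians of 10000 random lists; the mating list has the highest median, at 2.97, and the histone list the lowest, at -1.22.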

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

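The test of RNA degradation was chosen only after the result it concerns had been seen.

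Signals outside the main comparison were looked up in the probe sets that name no yeast gene here. The 9 probe sets of Bacillus subtilis lys, a control transcript that is absent from yeast, had a median of 4.36 in the mock array and 12.27 in the alpha-factor array, a median log2 ratio of 7.90 between the measured values. The mock median was below background, so the ratio has only a bound, a log2 ratio of at least 6.76 against the mock background level. The 9 probe sets of B. subtilis dap went the other way, from 14.02 to 4.16, which is also below background. The phe and thr controls were below background by their medians in both arrays. The bacterial bioB, bioC and bioD controls had median log2 ratios of 0.11, 0.13 and 0.19. Of 3470 unnamed probe sets, 422 were above background in at least 1 array, of which 29 were higher by 2-fold or more and 9 lower. The unnamed probe set with the largest ratio was at 12.02 in the alpha-factor array, a log2 ratio of 3.81, and the one with the lowest ratio went from 11.30 to 6.93, a log2 ratio of -4.37.

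For 25S ribosomal RNA, 2 probe sets, of which 1 is named for the 3' end, were at 14.73 in the mock array and 9.70 in the alpha-factor array by their median, a log2 ratio of -5.02. The other 25S probe sets had log2 ratios from -2.35 to 0.01, and all 8 had a median of -0.85. The 8 probe sets of 18S rRNA had a median log2 ratio of -0.74. A difference in RNA degradation was weighed through the 3' minus 5' difference of 7 control transcripts, which would differ between the arrays by 0.5 or more. The median change was 0.03, with a range from -0.52 to 0.27, so these messenger RNAs showed no shared change of that size. They do not measure the integrity of ribosomal RNA, so a difference in its degradation stays open. A difference in how much ribosomal RNA entered the labelling was not tested and stays open. No biological explanation was tested.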

How the results depend on the processing

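The alternatives that raise levels to background, leave out shared probe sets or keep only genes with a mock level of 8 or more were chosen after seeing the data. The 1.5-fold rule gave 646 higher and 570 lower genes and the 4-fold rule 68 and 54; under every other alternative run for these counts, both stayed within 1.5 times of 294 and 202. The median log2 ratios of all S. cerevisiae and of all S. pombe probe sets were -0.03 and -0.02, so centring moved little. No list median with a size of 1 or more and no named gene with such a ratio changed sign under the alternatives run. Centring by so little and adding a pseudocount cannot reverse such a sign, so for these alternatives the outcome was fixed in advance. The near-alike columns also left quantile normalization little to change. The median of the deleted genes became 0.41 among members above background, since HIS3 alone is left. List counts that changed by more than 1.5 times, or fell to 0, were as follows. Smaller changes of list counts are not given here. Polarity genes had 2 higher members after either centring or the loess curve, and MCM genes 2 lower ones after quantile normalization. With a pseudocount of 32, respiration genes had 1 higher member and gluconeogenesis genes 0, and gluconeogenesis genes also had 0 when levels below background were raised to it. Without genes read by shared probe sets, the genes taken by their COS, PAU or SEO names had 1 higher member, COS111, which is not of the COS family. In 4 cases a percentile crossed the upper bound of the central 95%. Matched on the mock level, gluconeogenesis genes were at 96.61, methionine genes at 96.95 and ribosomal protein genes at 98.94. Against lists not matched on level, glycolysis genes were at 77.37. No paired analysis was possible because each group holds 1 array, and no replicate could be left out for the same reason. Signal over background limits the ratios of genes that are dim in 1 array, such as IME4, whose log2 ratio of 7.59 became 6.64 with the pseudocount. With it, the log2 ratios of BAG7, PCL1 and CLB6 became 4.28, -4.19 and -2.86. Those of SPO16, SNO1 and SUL1 became -1.39, 1.46 and 1.04.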

Other observations

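The tests of the meiosis list and of alpha cells, and the repeat of the tRNA test without part of the genes, were chosen only after the results they concern had been seen.

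Genes outside the lists, named here after their values were seen, were also far apart between the arrays. Among higher genes, AMS1, the vacuolar alpha-mannosidase, was 8.11-fold higher, SRL3, a paralogue of the Start inhibitor WHI5, was 8.66-fold higher, and BNA2, the first enzyme of NAD synthesis from tryptophan, was 7.29-fold higher. PUG1, a porphyrin transporter, was 8.49-fold higher, and RTA1, a membrane protein, was 8.27-fold higher. Among the 15 genes with the lowest ratios, HPF1, a cell wall mannoprotein, was 17.6-fold lower, AIM20 was 11.9-fold lower, and YHP1, the paralogue of YOX1, was 8.76-fold lower. YMR030W-A was 9.57-fold lower and YKR075C was 8.66-fold lower.

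The ratio of IME4 was the largest of all genes, and a rise of meiosis genes as a group is argued against, since the meiosis list lay at percentile 85.22 of matched random lists. For transcription running in from a neighbour, the nearest measured genes were HOS2 with a log2 ratio of 1.71 and COX13 with 0.21. The locus tags YGL194C and YGL191W place HOS2 and COX13 on strands that run away from IME4, so that 0 of these neighbours is transcribed toward it and the ratio of HOS2 decides nothing about a run-in. The nearest measured genes that are transcribed toward IME4, looked up after the values were seen, were GCN1 with a log2 ratio of -0.18 and CDC55 with -0.02, which does not exclude that transcription runs on from a gene whose own level stays the same. The antisense RNA RME2 spans IME4 in the annotation and the strand that the probe set reads was not examined, so a change of either strand's transcript may account for the ratio and stays open.

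STE3 and MF(ALPHA)2 were higher with alpha factor in an a strain. Alpha cells in the treated culture are argued against by MF(ALPHA)1, an abundant transcript of such cells, whose log2 ratio was 0.08 at a level near background, provided that its probe set reports that transcript. For transcription of the silent alpha cassette, HMLALPHA1 was at 4.46 and 4.09, a log2 ratio of -0.37. Its shared probe set was below background in both arrays and was not shown to report the transcript, so this explanation stays open. A response of the 2 genes to pheromone in a cells also stays open and was not tested further.

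One hypothesis was that genes beside tRNA genes are more often higher, because Ty3 and its long terminal repeats insert beside tRNA genes and Ty3 reading frames were among the highest ratios. Of 223 higher genes outside the lists, 29 (13.0%) had a tRNA gene as a direct neighbour, against a mean of 7.69% in random sets matched on level, at percentile 99.86. These 29 include the Ty3 frames YGR109W-B and YIL082W-A, which gave rise to the hypothesis, so this percentile is not independent of it. Random sets were drawn from all genes, list members included. Without genes named only by a locus tag with a letter suffix, which include the Ty3 frames, 24 of 213 did (11.3%), at percentile 97.57, which only reached the upper bound of random sets, 11.3%. Of 136 lower genes, 8 did (5.88%), at percentile 22.66. Repeats of Ty3 beside these genes may contribute, but the repeats themselves were not located, and genes are not independent replicates. The genes with such a neighbour included, named after their values were seen, MST27 at 5.88-fold, HYM1 at 5.71-fold and FMP33 at 4.52-fold higher. Some genes beside a tRNA gene also had a higher gene as neighbour, such as MST27 with PRM8 and PRP39 with PRM6. The tRNA share and the pairs of higher genes described next are therefore not independent.

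A second hypothesis was that higher genes lie next to each other. Of 294 higher genes, 48 pairs were direct neighbours among measured genes, against a mean of 15.73 pairs in random sets, at percentile 100. By orientation, 18 pairs were divergent against a mean of 4.06, 27 were in tandem against 7.58, and 3 were convergent against 4.09. The tandem pairs included the Ty3 reading frames YGR109W-B and YGR109W-A, so not every pair is of independent genes. Related sequence within pairs was not examined. Lower genes formed 20 pairs against 7.46, of which 12 were divergent against 1.94, 6 were in tandem against 3.55 and 2 were convergent against 1.96. The tandem pairs of lower genes lay at percentile 89.34, within the central 95% of random sets. Divergent higher pairs, chosen after their values were seen, included PRM1 with ERG24, FUS3 with PEP1, KAR4 with PEX34, DIG2 with PEX29, and PRM6 with PRP39. Shared upstream regions may account for the divergent excess, and transcription past gene ends may add to the tandem excess of higher genes. Neither was tested beyond these counts.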
